A study of Mus musculus with 2 samples.

How the data were processed

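Acetylation of lysine 27 of histone H3 (H3K27ac), a chromatin mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing in mouse hindbrain at embryonic day 14.5. Per the labels, replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34 embryos, both of mixed sex, with library fragments of 300 to 500 bp. The 2 biological replicates form 1 group, and the series as used here holds no second tissue, age or mark.

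The values start from 4 peak lists that the authors deposited on genome build mm10. Per the text descriptions deposited with the samples, each replicate's own list was called on that replicate's alignments against 1 control file. The pooled list was called on the alignments of both replicates with 2 control files, and the replicated list was derived from the pooled list and both replicate lists. The deposited signal value of each peak is the authors' own, in the narrowPeak layout, and its exact definition is not stated. The deposited significance of each peak is given by the authors as −log10 p and −log10 q values. The aligner, the peak caller and their thresholds are not given in the sources used here. The smallest −log10 p was 2.02 in the list of replicate 1 and 2.05 in that of replicate 2, so both lists reach down to weak peaks. Read counts are not in these lists, so sequencing depth is unknown and no value below carries an interval that needs it. Signal values were used to describe, rank or filter peaks within a list. Between the lists of the replicates, which are not on a shared scale, they were correlated and for a few genes are given side by side, and no mean over both lists is reported.

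Genes were the 21853 protein-coding genes of GENCODE release M21, which annotates the assembly that mm10 names, on chromosomes 1 to 19, X and Y, with 54361 annotated transcription start sites (TSSs). Overlaps were computed with bedtools 2.31.1, sequences were read with samtools 1.23.1 and pysam 0.24.0, and tests used scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 under Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

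A peak counted as found in the other replicate when an overlap covered at least 50% of either peak. Chance overlap came from 100 circular shifts of the peaks within each chromosome. A gene counted as marked when a replicated peak lay within 1 kb of any of its TSSs, and peaks farther than 1 kb from every protein-coding TSS were called distal. A gene list was compared with all other genes by a two-sided Fisher's exact test, and its mean number of distal peaks within 100 kb of the gene's 5′ end by a two-sided permutation test against 10000 random lists of its size. P-values were adjusted by the Benjamini-Hochberg method over the 31 lists of each kind of test, or over the 3 contrasts between lists. The smallest p that the random lists can give is 0.0002 before adjustment. Genes are not replicates, and neighbouring genes can share a peak, so each p describes a list within this peak set and not variation between embryos. Domains were replicated peaks joined within 12.5 kb and ranked by the base pairs that peaks covered.

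The gene lists, the tests and all alternatives but those said to be added were fixed before the data were examined. The 25 lists by symbol asked for 378 symbols, of which 375 matched a protein-coding gene; H19, Kcnq1ot1 and Meg3 did not, because they are noncoding. The other 6 lists were gene families taken by symbol. Some genes stand in several lists, such as Atoh1 and Zic1 in the hindbrain and granule lists, so the lists are not independent of each other. Genes named in the text are, for each list by symbol, up to 4 marked members with the highest signal and up to 4 unmarked members in alphabetical order. Also named are genes at the 10 largest domains, at the 10 peaks of highest signal and at the 5 widest peaks, and all Hox genes; any other gene is said to have been chosen after its values were seen. Family lists are given as counts.

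The overlap, list and distal steps were tested on simulated data. With 60.1% of 78428 peaks kept and the rest shifted, the overlap step found 60.7% for the comparison of replicates. Among 200 simulated lists of 15 genes over 21853 genes, the promoter list test called 96.0% of those made with 10% marked and 98.0% of those made with 90%, but 2.50% of those made with 53%. The distal list test, on unadjusted p, called 6.00% of 200 unchanged lists of 15 genes, 54.5% with counts multiplied by 2 and 90.0% with counts multiplied by 3.

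Alternatives covered the overlap rule, stricter peak thresholds, equal numbers of peaks, promoter windows of 500 bp and 2.5 kb, the gene 5′ end as only TSS, the pooled list, each replicate alone, random lists matched on promoter CpG content (observed over expected CpG within 500 bp of the 5′ end, in 10 classes), distances of 50 and 250 kb, and other ways of building domains. Comparisons of the contrasts within 3 classes of promoter CpG content and with 70000 peaks per replicate were added after the data were seen. The 9 replicated peaks on unplaced or unlocalised scaffolds were left out of all comparisons with genes.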

Results

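The data show where H3K27ac was found in embryonic mouse hindbrain, the part of the neural tube that forms the cerebellum, pons and medulla, at embryonic day 14.5. Both replicates came from separate pools of embryos. The list of replicate 1 held 78428 peaks covering 43.9 Mb and that of replicate 2 held 91165 peaks covering 48.9 Mb. The pooled list held 102453 peaks and the replicated list 51625 peaks, covering 49.5 Mb with a median width of 657 bp. All coordinates are on mm10, and signal values are those the authors gave each peak.

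The first comparison asks which transcription factors of the brain's regions carried the mark. Of 36 transcription factors of the hindbrain and rhombic lip, 31 (86.1%) had a replicated peak at a promoter, against 6 of 27 forebrain factors (22.2%). The strongest hindbrain members were the homeobox genes Meis1 (signal 38.9, chr11:19006007-19022005) and Meis2 (33.6, chr2:116055084-116077062). Zic1 and Zic4, zinc finger genes transcribed away from each other, shared a peak of 12327 bp with a signal of 22.4 (chr9:91359935-91372261). The marked forebrain members had lower signals, led by Lhx2 (9.09), Otp (8.35), Neurod6 (7.50) and Satb2 (5.97).

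Forebrain genes without a promoter peak included Dlx1, Dlx2 and Dlx5, which act in forebrain interneurons, and Arx. The nearest replicated peak lay 61778 bp from a TSS of Dlx1, 63728 bp from Dlx2, 73340 bp from Dlx5 and 345237 bp from Arx. The unmarked hindbrain members were Atoh1, Egr2, Pax7 and Phox2a, and also Ptf1a, named here after its value was seen. Atoh1, which specifies cerebellar granule cell precursors, had its nearest peak 1157 bp from a TSS, just outside the promoter window. The conditional odds ratio between the hindbrain and forebrain lists was 20.2 (95% confidence interval 5.06 to 99.999), with a Fisher's exact adjusted p of 5.58e-07 over 3 contrasts. Each replicate's own list gave 86.1% for the hindbrain factors, with 22.2% and 25.9% for the forebrain factors in replicates 1 and 2. Against all other genes, of which 53.4% were marked, the hindbrain list was higher (Fisher's exact adjusted p = 0.000256 over 31 lists) and the forebrain list lower (adjusted p = 0.00309). Against random lists matched on promoter CpG content the hindbrain call was lost (matched share 77.7%, permutation adjusted p = 0.337), and the forebrain call was not (67.3%, permutation adjusted p = 0.00103).

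The Hox genes, whose order along each cluster follows their order of expression along the body axis, were marked at the 3′ ends of the clusters. In paralog groups 1 to 5, 13 of 15 genes (86.7%) had a promoter peak, against 5 of 8 (62.5%) in groups 6 to 8 and 1 of 16 (6.25%) in groups 9 to 13. The widest peak of the whole list, 45990 bp at chr11:96301553-96347542, spanned the promoters of Hoxb3, Hoxb4 and Hoxb5 with a signal of 36.9. In the replicates' own lists, which are not on a shared scale, the signal at these 3 promoters was 18.6 and 37.5. The second widest, 33412 bp at chr6:52158377-52191788, reached the promoters of Hoxa1, Hoxa2, Hoxa3 and Hoxa4 with a signal of 42.4. That value belongs to the merged peak: at Hoxa1 the signal was 4.68 in replicate 1 and 40.4 in replicate 2, and at Hoxa2 33.6 and 40.4. The signal was 19.1 at Hoxa5 and 9.87 at Hoxa6, and no replicated peak lay at the promoters of Hoxa7, Hoxa9, Hoxa10, Hoxa11 or Hoxa13.

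In the HoxB cluster the signal was 32.5 at Hoxb2, 10.2 at Hoxb6, 5.72 at the peak shared by Hoxb7 and Hoxb8, and 3.90 at Hoxb9, the only marked member of groups 9 to 13. Hoxb1 and Hoxd1 were the unmarked members of groups 1 to 5, with the nearest peak 8917 bp and 9295 bp away. HoxC and HoxD carried peaks at Hoxc4 (17.8), Hoxc5 (16.2), Hoxc6 (3.54), Hoxd3 (29.0) and Hoxd4 (13.8). Groups 1 to 5 and 9 to 13 differed with a conditional odds ratio of 72.6 (95% confidence interval 6.33 to 4400.4) and a Fisher's exact adjusted p of 6.84e-06, and both replicates gave the same shares. The 13 marked genes of groups 1 to 5 rested on 14 separate peaks, several of them shared, so the genes were not independent of each other. Against all other genes, groups 1 to 5 were higher (Fisher's exact adjusted p = 0.0153), groups 9 to 13 lower (adjusted p = 0.000428) and groups 6 to 8 not different (adjusted p = 0.732). With CpG-matched lists the call for groups 1 to 5 was lost (permutation adjusted p = 0.159). The difference of groups 6 to 8 from background turned from 9.06 points to −7.50 with these lists and to −0.455 with the gene 5′ end as only TSS.

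**Figure D1:**
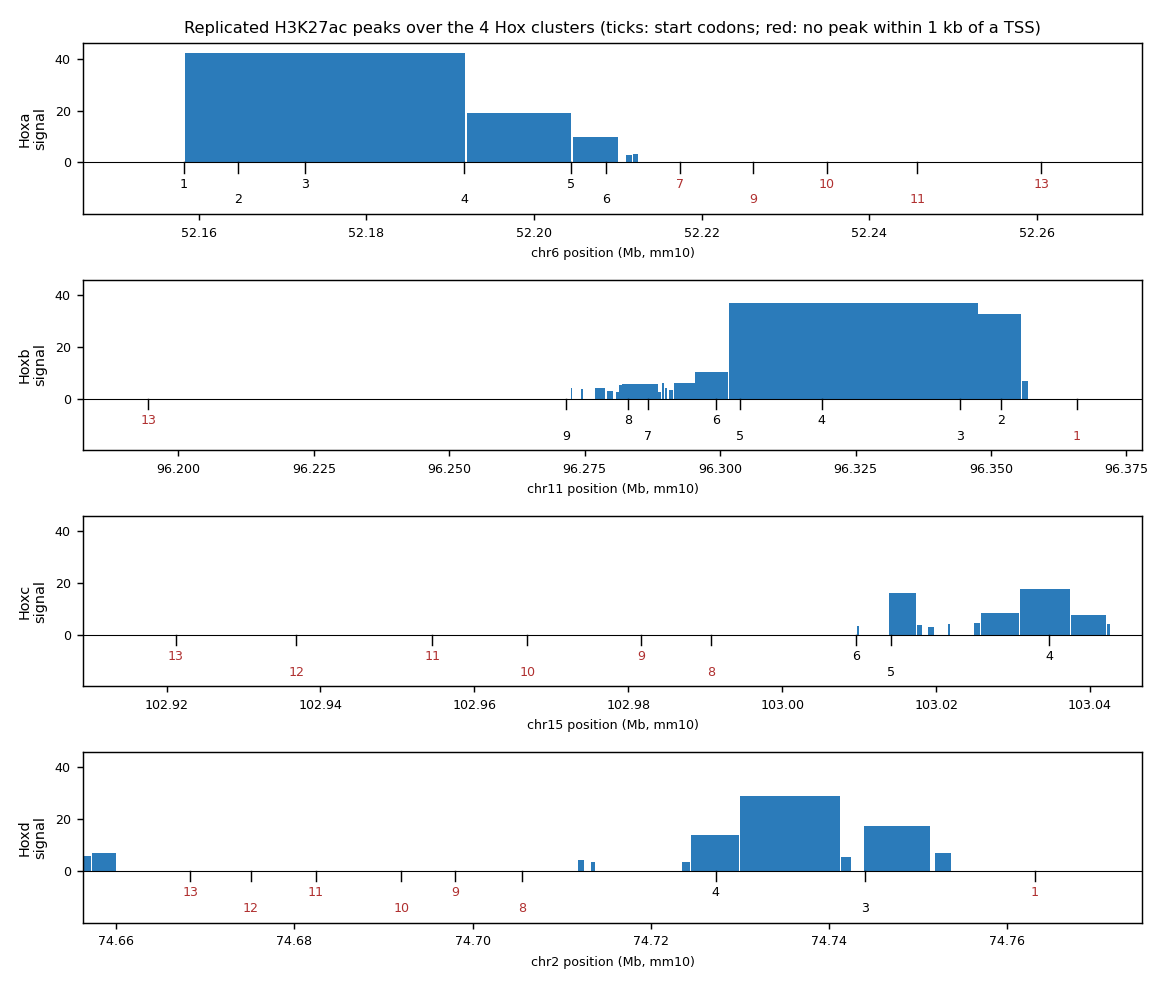
Replicated H3K27ac peaks over the 4 Hox clusters, with position in Mb on mm10 along each horizontal axis and the authors' signal value on the vertical axis; ticks mark start codons, numbers give the paralog group, and red numbers are genes with no peak within 1 kb of a TSS. Peaks cover groups 1 to 5 except Hoxb1 and Hoxd1, and 1 of the 16 genes of groups 9 to 13 is marked.

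Genes of neurons and neural progenitors were nearly all marked, and genes of tissues outside the brain mostly were not. Promoter peaks were present at 39 of 40 neuronal and progenitor genes and at 5 of 45 liver, skeletal muscle and germline genes (11.1%). All 20 neuronal genes were marked, with the highest signals at the adhesion gene Ncam1 (35.1), the tubulin gene Tubb3 (29.3) and the microtubule-associated genes Map2 (28.6) and Mapt (28.3). Of the 20 progenitor genes 19 were marked, led by the RNA-binding protein gene Msi1 (54.5, chr5:115428670-115439239), the Notch ligand gene Dll1 (16.3), Sox2 (14.8) and the Notch target Hes5 (14.7). Neurog1 had no replicated promoter peak, although replicate 2 alone listed a peak there with a signal of 3.61.

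The liver list was marked at Foxa3 only (5.75), with Afp, Ahsg, Alb and Apoa1 among the 14 unmarked genes. Skeletal muscle genes were marked at Mylpf (10.2), Casq1 (5.71) and Actn3 (5.53), with Acta1, Ckm, Myf5 and Myf6 among the 12 unmarked. The germline list was marked at Dazl only (4.28), with Acrv1, Ddx4, Dmc1 and Mael among the 14 unmarked. The contrast had a conditional odds ratio of 268 (95% confidence interval 33.3 to 12921) and a Fisher's exact adjusted p of 5.69e-17. Against all other genes the neuronal list (Fisher's exact adjusted p = 1.69e-05) and the progenitor list (adjusted p = 0.000428) were higher. The liver and germline lists (Fisher's exact adjusted p = 0.000704 each) and the muscle list (adjusted p = 0.0247) were lower. With CpG-matched lists the liver and muscle calls were lost (permutation adjusted p = 0.294 and 0.502), and the progenitor difference narrowed from 41.6 to 21.1 points. A window of 2.5 kb ended the muscle and germline calls (Fisher's exact adjusted p = 0.0514 each), with differences that moved from −33.5 and −46.8 points to −28.2 points each.

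Among the neural cell types, genes of cerebellar granule cells and Sonic hedgehog signalling were marked at 18 of 20 promoters (Fisher's exact adjusted p = 0.00248). The highest signals in that list were at Nhlh2 (32.0), the hedgehog receptor gene Ptch1 (26.1), Zic1 and Mycn (21.2), while Atoh1 and Hhip were unmarked. All 10 genes of the inhibitory transmission list were marked (Fisher's exact adjusted p = 0.00409), led by the GABA-synthesis genes Gad2 (22.5) and Gad1 (19.5), the vesicular transporter gene Slc32a1 (18.4) and Lhx5 (16.5). Lhx5 and some other members of that list are transcription factor genes that also stand in the hindbrain list. Glutamatergic genes were marked at 7 of 10 promoters, including the transporter gene Slc17a6 (25.6), Gls (19.1), Gria2 (18.7) and Grid2 (13.9), but the list did not pass the exact test (adjusted p = 0.393). Slc17a7, Slc17a8 and Grm1 were unmarked. The granule call ended when only the gene 5′ end counted as TSS, where the difference moved from 36.6 to 24.6 points (Fisher's exact adjusted p = 0.0559).

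Astrocyte genes were marked at 8 of 12 promoters (Fisher's exact adjusted p = 0.415), with Id4 (23.7), Nfib (19.6), Slc1a2 (19.3) and Nfia (15.2) highest. The late markers Gfap and Aqp4 were unmarked, as were Aldh1l1 and S100b. Oligodendrocyte genes were marked at 4 of 12 (Fisher's exact adjusted p = 0.283), at low signals of 4.27 for Mbp, 3.54 for Cnp, 3.53 for Sox10 and 3.22 for Pdgfra, with Cspg4, Mag, Mobp and Mog unmarked. Monoaminergic genes were below background at 2 of 12 (Fisher's exact adjusted p = 0.0247), Maoa (12.4) and Ddc (3.29), and the noradrenaline-synthesis gene Dbh and the serotonergic factor gene Fev had no peak, nor did Gch1 and Maob. That call ended with a 2.5 kb window, where the difference moved from −36.8 to −29.9 points (Fisher's exact adjusted p = 0.0599). Ddc had no promoter peak in the own list of replicate 1. Motor and cholinergic genes were marked at 3 of 12, Phox2b (5.43), Ret (3.31) and Lhx4 (2.77), without passing the exact test (adjusted p = 0.101). Lhx4 likewise had no promoter peak in the own list of replicate 1. Chat, Isl1, Isl2 and Lhx3 were unmarked, and the list was called lower with a 500 bp window (Fisher's exact adjusted p = 0.0235) and with the 5′ end only (adjusted p = 0.0333). With only peaks above the median −log10 p, the oligodendrocyte and motor lists were both called lower (Fisher's exact adjusted p = 0.00112 and 0.00951). In the pooled list the oligodendrocyte difference turned from −20.1 to 1.08 points, with 7 of 12 genes marked (Fisher's exact adjusted p = 1), and the motor difference narrowed from −28.5 to −15.6 points.

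Genes of other cell types that a dissected hindbrain can hold gave mixed results. Endothelial genes were marked at 8 of 12 promoters with signals no higher than 4.45 at Egfl7, 4.08 at Cdh5 and Cldn5 and 3.95 at Kdr (Fisher's exact adjusted p = 0.415); Flt1, Sox17, Tek and Tie1 were unmarked. With only peaks above the median −log10 p, the endothelial list was below background (difference −48.8 percentage points, Fisher's exact adjusted p = 0.00112), whereas in the pooled list it was 34.4 points above (Fisher's exact adjusted p = 0.0283) and with the 5′ end only −0.456 points from it. Pericyte, meningeal and mesenchymal genes were marked at 4 of 14 (Fisher's exact adjusted p = 0.130), Foxc1 (7.61), Pdgfrb (4.45), Col1a1 (3.68) and Tbx18 (3.34). The shares of the 2 replicates lay farthest apart for this list among all 31, with 3 of 14 marked in replicate 1 and 9 of 14 in replicate 2. In replicate 1 alone the list was called lower (difference −32.8 points, Fisher's exact adjusted p = 0.0223), and in replicate 2 alone it lay 8.82 points above background without passing (Fisher's exact adjusted p = 0.639). With only peaks above the median −log10 p it was called lower (difference −34.5 points, Fisher's exact adjusted p = 0.0179), and in the pooled list it lay 7.04 points above background (adjusted p = 0.873). Col1a2, Col3a1 and Dcn had a promoter peak in replicate 2 only, and Abcc9 in neither.

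Microglial and myeloid genes were below background at 1 of 12, C1qb (3.53; Fisher's exact adjusted p = 0.00378), with Aif1, C1qa, C1qc and Csf1r unmarked. Erythroid genes were also at 1 of 12 (Fisher's exact adjusted p = 0.00378), with the transferrin receptor gene Tfrc at 15.3 and Alas2, Epor, Gata1 and Gypa unmarked. Both calls were lost against CpG-matched lists (matched shares 17.9% and 23.4%, permutation adjusted p = 0.719 and 0.321). The microglial call was also lost in replicate 2 alone (Fisher's exact adjusted p = 0.0592), though there 3 of 12 (25%) were marked against 55.5% of all genes. Choroid plexus and ependymal genes were marked at 4 of 12 (Fisher's exact adjusted p = 0.283), Foxj1 (6.75), Enpp2 (5.67), Otx2 (5.34) and Ttr (4.27), with Aqp1, Cldn1, Clic6 and Folr1 unmarked. In the pooled list 7 of these 12 genes were marked and the difference turned from −20.1 to 1.08 points (Fisher's exact adjusted p = 1).

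Housekeeping genes were marked at 14 of 15 promoters (Fisher's exact adjusted p = 0.00299), with Actb (66.1), Ywhaz (57.6), Eef1a1 (41.5) and Ubc (37.3) highest and Gusb unmarked. Of 17 imprinted genes 14 were marked (Fisher's exact adjusted p = 0.0360), led by Gnas (39.9), Peg3 (26.5), Impact (25.1) and Ube3a (17.9), and Dlk1, Igf2 and Ndn were unmarked. Immediate early genes were marked at 12 of 15 (Fisher's exact adjusted p = 0.0893), led by Dusp1 (32.2), Jun (16.5), Btg2 (14.4) and Ier2 (9.33), with Atf3, Fosb and Hspa1a unmarked. The imprinted call ended in the pooled list, where the difference moved from 28.9 to 25.1 points (Fisher's exact adjusted p = 0.0615), and with the gene 5′ end as only TSS, where it narrowed to 14.3 points (adjusted p = 0.381), and the housekeeping call against CpG-matched lists (permutation adjusted p = 0.0784). Immediate early genes passed the test with a 2.5 kb window, with the 5′ end only, in the pooled list and in replicate 1 alone (Fisher's exact adjusted p = 0.0261, 0.0496, 0.0465 and 0.0223).

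Gene families differed widely. Ribosomal protein genes were marked at 87 of 98 promoters (Fisher's exact adjusted p = 8.43e-13) and replication-dependent histone genes at 53 of 64 (adjusted p = 6.31e-06). Marked promoters were found for 2 of 1134 olfactory receptor genes, where the exact p was too small for the software to represent, and for 1 of 331 vomeronasal receptor genes (adjusted p = 4.32e-108). Clustered protocadherins were marked at 13 of 57 (Fisher's exact adjusted p = 1.67e-05) and keratins at 4 of 53 (adjusted p = 1.15e-11). In the pooled list 23 of the 57 protocadherins were marked, and the difference narrowed from −30.7 to −16.9 points (Fisher's exact adjusted p = 0.0186). Against CpG-matched lists the histone genes were no longer higher (difference −5.60 points, permutation adjusted p = 0.289). CpG matching also narrowed the differences of olfactory receptors from −56.2 to −8.26 points, vomeronasal receptors from −54.0 to −7.45, keratins from −46.0 to −23.04 and ribosomal protein genes from 35.5 to 12.2. Their calls were kept (permutation adjusted p = 0.00103, 0.00103, 0.00155 and 0.00155). Over all 31 lists, 10 were above background, 12 below and 9 not called. Against CpG-matched lists 6 were above and 8 below, and with only peaks above the median −log10 p 10 were above and 16 below.

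**Figure D2:**
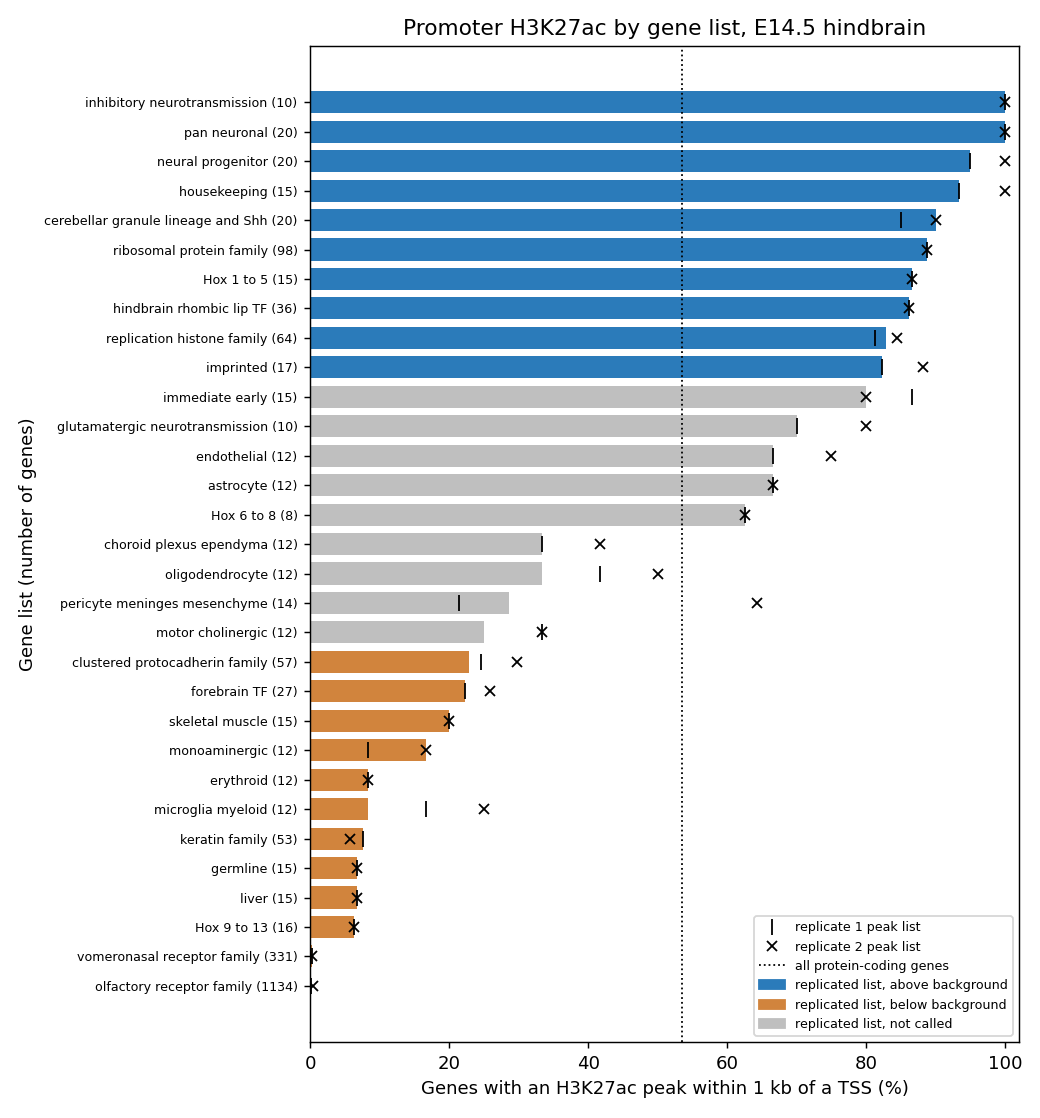
Percent of genes with an H3K27ac peak within 1 kb of a TSS (horizontal axis) for each of the 31 gene lists (vertical axis, number of genes in parentheses); bars are the replicated list, vertical marks and crosses are the lists of replicates 1 and 2, and the dotted line is the share of all protein-coding genes, 53.4%. The hindbrain factors stand at 86.1%, the forebrain factors at 22.2%, and the 2 replicates are farthest apart for pericyte, meningeal and mesenchymal genes, at 21.4% and 64.3%.

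Distal peaks were more numerous than around random genes for several neural lists, but not for all of them. Genes of inhibitory transmission had a mean of 10.9 ± 8.82 (SD over 10 genes) distal peaks within 100 kb, against 3.06 for random lists of that size (permutation adjusted p = 0.00103). Astrocyte genes followed with 9.58 ± 7.90 (n = 12 genes, permutation adjusted p = 0.00155), although their promoter test was not passed. Hindbrain factors had 8.89 ± 7.48 (n = 36, permutation adjusted p = 0.00103), progenitor genes 8.70 ± 6.83 (n = 20, adjusted p = 0.00155), granule and hedgehog genes 8.35 ± 6.89 (n = 20, adjusted p = 0.00103) and neuronal genes 6.65 ± 5.99 (n = 20, adjusted p = 0.0101). Among the list members named in the text, Meis2 and Id4 each had 20 such peaks, Zic1 and Ier2 19, Zic4 and Ndn 18 and Aldh1l1 17, and Ndn and Aldh1l1 had no promoter peak.

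Imprinted genes (mean 8.29, permutation adjusted p = 0.00207), Hox groups 1 to 5 (7.53, adjusted p = 0.00682) and immediate early genes (6.27, adjusted p = 0.0475) were above random lists as well. The immediate early call ended in the pooled list, in either replicate alone and within 250 kb, and the progenitor call within 250 kb (permutation adjusted p = 0.0509). Glutamatergic (mean 2.20, permutation adjusted p = 0.731), motor (2.67, adjusted p = 0.879), monoaminergic (3, adjusted p = 0.970) and oligodendrocyte genes (4.25, adjusted p = 0.506) did not differ from random lists. Forebrain factors had a mean of 2.22 distal peaks, which did not differ from 3.07 for random lists (permutation adjusted p = 0.451). Lower means were found for olfactory receptors (0.298), vomeronasal receptors (0.0997) and keratins (0.811), each with a permutation adjusted p of 0.00103. In total 9 lists were higher, 3 lower and 19 not called, among them Hox groups 6 to 8 at 7.13 (permutation adjusted p = 0.0642) and Hox groups 9 to 13 at 5.13 (permutation adjusted p = 0.173). Groups 6 to 8 were called higher in 6 of 8 alternatives, among them 50 kb (ratio 3.27 to random lists, permutation adjusted p = 0.0137), 250 kb (2.25, adjusted p = 0.0305) and lists matched on TSS density (2.51, adjusted p = 0.0196). For groups 9 to 13 the ratio was 1.29 within 50 kb (permutation adjusted p = 0.662) and 2.32 within 250 kb (adjusted p = 0.00248), and they were also called higher in each replicate alone and with only peaks above the median −log10 p. Clustered protocadherins, not called at 100 kb, were called lower within 50 kb (ratio 0.474, permutation adjusted p = 0.0137), and replication histones higher with only peaks above the median −log10 p (1.88, adjusted p = 0.00248). Hox genes of a cluster lie close together and counted many of the same distal peaks, such as 5 at each of Hoxd9 to Hoxd13. Random lists drew genes from the whole genome, so the distal p-values of the Hox lists are too small. The same limit holds for other lists whose genes lie in clusters.

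The 10 largest acetylated domains included the HoxB and HoxA clusters. The first, at chr11:88232474-88729571, held 169 peaks covering 204156 bp. It overlapped Msi2, an RNA-binding protein gene of the Musashi family, and Ccdc182. The HoxB domain, chr11:96272401-96356835, was covered over 92.8% of its span, and the HoxA domain, chr6:52158377-52212443, over 97.0%. Others of the 10 largest lay over Gse1 with Gm20388, Zmiz1, the tyrosine kinase gene Fyn, the corepressor gene Ncor2, the neighbours Myo18a, Pipox and Sez6, the transcription factor gene Ebf3, and 1700001O22Rik with Ntmt1. In total 24527 domains were formed, of which 111 had at least 20 kb covered by peaks, and no test applied to their ranks.

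The highest signal of the replicated list, 78.7, was at the promoter of the histone methyltransferase gene Kmt5b (chr19:3766541-3769387). Promoters of Actb (66.1), Zc3h4 (65.8), Zfp532 (62.6), Tnrc18 (62.5), Atf1 (62.2), Epc1 (61.3) and Actg1 (60.8) followed. The other two of the 10 were intergenic by protein-coding annotation, a peak of 28395 bp at chr13:83714526-83742920 with a signal of 61.6, 210492 bp from Mef2c, and a peak 5927 bp from Spen with 59.6. The third widest peak, 30372 bp at chr7:79498884-79529255, was likewise intergenic and 32522 bp from Polg, and the fifth, 21979 bp, covered the promoter of Meis2.

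Over the whole replicated list, promoters took a larger share of peaks than chance. Of 51616 peaks on the assembled chromosomes, 14461 (28.0%) lay within 1 kb of a protein-coding TSS, against a mean of 3.72% and a maximum of 4.20% after 100 shifts. Introns held 39.9% of peaks, intergenic sequence 29.8%, untranslated regions 1.19% and coding exons 1.06%. Promoter peaks were wider than distal peaks, with medians of 996 and 581 bp, and had median signals of 8.24 and 3.86. Of the 21853 protein-coding genes, 11678 (53.4%) were marked, compared with 54.2% in replicate 1 and 55.5% in replicate 2, and 11450 genes were marked in both replicates' own lists. Promoter shares were lower in the replicates' own lists, 22.4% and 20.2%, and rose to 46.1% among replicated peaks above the median −log10 p.

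Under the overlap rule used, the replicates shared nearly all of their strong peaks and few of their weak ones. Of the strongest 10% of peaks by −log10 p, 99.99% of those in replicate 1 and 99.98% of those in replicate 2 were found in the other replicate, compared with 30.0% and 19.2% of the weakest 10%. Over all peaks, 56.9% of replicate 1 (Wilson 95% interval 56.5 to 57.2) and 48.6% of replicate 2 (48.3 to 48.9) were found in the other, far above the chance means of 2.82% and 2.45%. These intervals cover counting error only. Chance overlap was not computed for each 10% class. A peak also counted as found when a narrower peak of the other replicate lay within it, which can favour wide peaks. With the overlap required of both peaks, the shares over all peaks were 37.9% for replicate 1 and 32.6% for replicate 2. The classes were not compared under that rule, so the part of peak width in the fall from strong to weak peaks was not tested. Across 44619 overlapping pairs the signal values correlated with a Spearman rho of 0.642 and a Pearson r of 0.765 on the log2 scale, a description across peaks, which are not independent replicates. Of the 20000 strongest peaks of each replicate, 79.8% and 80.1% were shared.

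**Figure D3:**
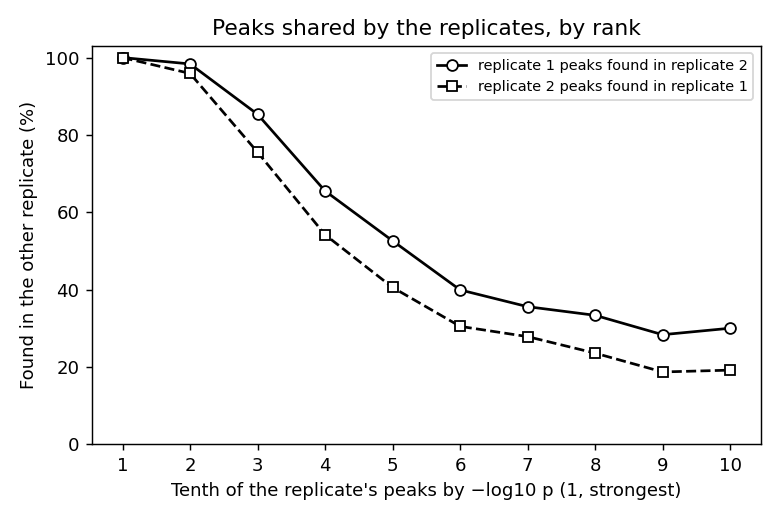
Percent of a replicate's peaks found in the other replicate (vertical axis) in 10 equal classes of its peaks ranked on −log10 p, from 1, the strongest, to 10 (horizontal axis); circles are replicate 1 and squares replicate 2. The share falls from 99.99% to 30.0% in replicate 1 and from 99.98% to 19.2% in replicate 2.

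The replication step kept 51625 of the 102453 pooled peaks (50.4%). Kept peaks had a median signal of 4.27 and a median width of 657 bp, and dropped peaks 2.77 and 235 bp, with no dropped peak above a signal of 5.38. All 41820 pooled peaks found in both replicates were in the replicated list. A further 9805 replicated peaks did not meet the 50% overlap in both replicates, and 464 of these met it in neither.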

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

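No explanation was tested in this part, so no test was chosen after the result was seen. The replicated list held 9 replicated peaks on scaffolds outside the assembled chromosomes, a signal in data that no comparison with genes used and more than the 3 that a count of 0 allows. No control level for scaffolds was available, and the lists of replicate 1, replicate 2 and the pool held 9, 11 and 14 such peaks, so the count alone does not set these peaks apart. The strongest, 2089 bp wide with a signal of 52.99, lay on an unlocalised scaffold of chromosome 4, and the next, 915 bp wide with a signal of 16.5, on an unlocalised scaffold of chromosome X.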

How the results depend on the processing

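The comparison of the 3 contrasts within classes of promoter CpG content and that with 70000 peaks per replicate were chosen after results were seen. In every alternative run, each of the 3 contrasts between gene lists kept its direction and its adjusted p under 0.05. Within classes of promoter CpG content they were 63.7 points for hindbrain against forebrain factors, 80.9 for Hox groups 1 to 5 against 9 to 13 and 82.5 for neural against other tissue genes, with two-sided permutation p of 1e-05, 4e-05 and 1e-05, where 1e-05 is the smallest that 100000 permutations can give. Median promoter CpG content was 0.677 for the neural and 0.279 for the other tissue genes. The 3 broad classes can leave part of that gap within each class, so CpG content is not excluded as part of the neural contrast. Of 279 alternatives of the promoter list tests 245 kept direction and call, 14 lost the call, 11 gained it and 9 reversed. Of 248 alternatives of the distal list tests 214 kept both, 5 lost the call, 12 gained it and 17 reversed. Sequencing depth is unknown, so what it limits was not tested, and unless stated the cause was not tested.

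An overlap of at least 1 bp gave 64.2% of replicate 1 peaks and 54.9% of replicate 2 peaks found in the other, a Spearman rho of 0.607, and 81.7% of replicated peaks found in both. An overlap of 50% of both peaks gave 37.9%, 32.6%, 0.789 and 50.6%. Peaks above the median −log10 p of each list gave 69.8%, 60.3%, 0.705 and 98.4%, with 85.9% of pooled peaks kept. A −log10 q of at least 2 gave 60.03%, 52.4%, 0.670 and 81.5%, with 59.8% of pooled peaks kept. At these thresholds the overlap between replicates and the rho used filtered lists on each side. The shares of replicated peaks found in both replicates and of pooled peaks kept compared filtered peaks with the full, unfiltered lists. The 20000 strongest peaks of each replicate gave 79.8% and 80.1%, and −log10 p in place of the signal gave a rho of 0.705.

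The promoter share of peaks and the share of genes marked were 26.5% and 52.7% with a 500 bp window, 31.2% and 54.8% with 2.5 kb, and 23.6% and 50.5% with the 5′ end only. They were 17.8% and 57.3% in the pooled list and 46.1% and 48.8% above the median −log10 p. In the lists of single replicates they ranged from 20.2% to 22.4% and from 54.2% to 55.5%. With CpG-matched random lists 6 lists were higher, against 10 compared with all other genes.

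Promoter differences from background that reversed were, with the 5′ end only, −0.455 points for Hox groups 6 to 8 and −0.456 for endothelial genes. In the pooled list they were 1.08 for oligodendrocyte genes, 7.04 for mesenchymal genes and 1.08 for choroid plexus genes. Above the median −log10 p the endothelial difference was −48.8. CpG-matched lists gave −7.50 for Hox groups 6 to 8 and −5.60 for replication histones. In single replicates the mesenchymal difference ranged from −32.8 to 8.82. Of these results only replication histones had been called.

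Ratios of distal peaks to random lists that reversed were, within 50 kb, 1.00 for monoaminergic, 1.11 for mesenchymal, 0.838 for erythroid and 0.954 for choroid plexus genes. Within 250 kb they were 0.836 for endothelial and 0.850 for choroid plexus genes, and with lists matched on TSS density 0.982 for choroid plexus genes. The pooled list gave 1.13 for monoaminergic, 1.16 for motor and 0.873 for replication histone genes. Peaks above the median −log10 p gave 0.982 for oligodendrocyte and 0.662 for choroid plexus genes. In single replicates the ratios ranged from 1.03 to 1.10 for monoaminergic, from 1.06 to 1.18 for motor and from 0.930 to 1.19 for replication histone genes. None of these ratios had been called before.

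Of the 20 largest domains, 12 were still among the 20 largest when peaks were joined within 5 kb, 12 when domains were ranked by span and 12 in the pooled list.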

Other observations

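The use of forebrain genes in the pooled list to test loss at the replication step, though that list was among the alternatives fixed beforehand, and the tests of X-linked and autosomal genes with families left out on all chromosomes, of both X adjustments together and of words without CG were chosen after results were seen, as were the exact tests of the first mesenchymal list and the use of 70000 peaks per replicate. The microRNA genes below were chosen after their values were seen.

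Some of the widest peaks covered microRNA genes, and no test of enrichment was run for them. The 30372 bp peak on chromosome 7 covered Mir9-3 (chr7:79505264-79505353) and was the third widest of all replicated peaks. The 28395 bp peak on chromosome 13 covered Mir9-2 (chr13:83738814-83738885) and ranked 4th. The other copy of this microRNA, Mir9-1 (chr3:88215598-88215686), lay under the peak ranked 6th, 18750 bp wide with a signal of 18.9. The copies of miR-124, a microRNA abundant in neurons, lay under peaks of 16820 bp at Mir124a-1 (signal 42.4), 16205 bp at Mir124a-2 (53.4) and 9876 bp at Mir124a-3 (35.6), ranked 8th, 11th and 53rd by width. Peaks of 13503 and 7575 bp covered Mir125b-1 and Mir125b-2. Other microRNA genes shared these or similarly wide peaks, among them Mir3093 with Mir9-1, Mir3078 with Mir124a-1, and Mir3089 under a peak ranked 39th. Gm25641 (chr3:88215589-88215696) is a further annotation over the bases of Mir9-1. The widest peak, over the promoters of Hoxb3, Hoxb4 and Hoxb5, held Mir10a, and Mir10b lay under a peak of 5321 bp at Hoxd4. Of 2202 annotated microRNA genes, 220 (9.99%) overlapped a replicated peak, and some of these annotations cover the same bases.

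Distal peaks were rich in sequence words that contain CG and in AT-rich words, among them the homeodomain word TAATTA. The hypothesis that neural transcription factor words mark distal acetylated regions was tested with CAGCTG, CAGATG, TAATTA and ACAAAG, each of which would then rank in the top 5% of 2080 words of 6 bases. Over 37154 distal peaks and 63352 flanking windows weighted to the same GC content, only 1 of the 4 did so, and fewer than 2 had been set beforehand as the result that would count against the hypothesis. TAATTA ranked 27th at 1.74 times its flanking frequency, ACAAAG 202nd at 1.34 times, CAGCTG 224th at 1.32 times and CAGATG 940th at 1.05 times. That bound was not sound for this ranking, because the GC weighting does not balance CG and the 10 highest-ranked words all contained it. The counted bases were also not matched on GC, because repeats were left out of the word counts but not of the GC weights. Among the 1476 words without CG, TAATTA ranked 1st, ACAAAG 28th, CAGCTG 31st and CAGATG 434th, so 3 of the 4 were in the top 5% and CAGATG was outside it in both rankings. The similar words ATTAAT (1.66 times) and AATTAA (1.59 times) ranked 2nd and 3rd there, so TAATTA did not stand alone. The second ranking was chosen after the first was seen and cannot count in favour, so the hypothesis stays open for the other 3 words and is not supported for CAGATG.

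Fewer forebrain factors than other genes had a promoter peak. Promoter CpG content is argued against by the matched random lists, which held 67.3% marked genes against 22.2% (two-sided permutation p = 0.00020, the smallest these lists can give). These promoters were not low in CpG, with a median of 0.655 against 0.569 for autosomal genes. The matched share also lay above the 53.4% of all genes. CpG content thus pointed to more marked promoters and not fewer, so this test ruled out little. Loss at the replication step is argued against by the pooled list, where 6 of the 27 were marked as well (Fisher's exact p = 0.00029). No second tissue was measured here, so a biological explanation by the region dissected was not tested against another region and stays open as a hypothesis.

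More mesenchymal genes had a promoter peak in replicate 2 than in replicate 1. In the fixed list 6 of 14 were marked in replicate 2 alone and 0 in replicate 1 alone, the 6 being Col3a1, Dcn, Twist1, Col1a2, Foxc2 and Tbx18, of which Twist1 and Foxc2 are named after their values were seen (two-sided exact binomial p = 0.0313, on genes that showed the pattern, and two-sided Fisher's exact p = 0.0893 against all other genes, since over all genes 673 were marked in replicate 2 alone and 404 in replicate 1 alone). A second list of 35 mesenchymal and meningeal genes, written before its values were seen, had 5 in replicate 2 alone and 0 in replicate 1 alone (two-sided exact binomial p = 0.0625, the smallest that 5 genes allow, and Fisher's exact p = 0.164 against all other genes), so more such cells in the pool of replicate 2, for which the labels name no sort, cannot be told apart from chance. With 70000 peaks each, the first list still had 6 against 1 (exact binomial p = 0.125), and the second had 2 against 1 (Fisher's exact p = 1 against all other genes, for which the smallest attainable p was 0.101), so the larger peak list of replicate 2 stays open too. The signals of the 3 members marked in both own lists, which are not on a shared scale, were 5.30 and 8.86 for Foxc1, 3.83 and 4.52 for Pdgfrb and 3.06 and 2.44 for Col1a1, in replicates 1 and 2.

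Fewer X-linked than autosomal promoters were marked, 39.1% of 948 against 54.5% of 20722 (odds ratio 0.536, 95% interval 0.469 to 0.612), and distal peaks were sparser on the X, 2.39 against 14.9 per Mb. Promoter CpG content, as measured at the gene 5′ end in 10 classes, is argued against as the whole cause by the odds ratio within these classes, 0.754 (0.637 to 0.892). A gene could be marked at any TSS, and CpG content at other TSSs or within a class was not adjusted for. CpG content as the whole cause is therefore not excluded. Multicopy families as the whole cause are argued against by 0.767 (0.655 to 0.898) with genes of these symbols left out on all chromosomes. The test first set out left them out on the X only, which raises the ratio by construction, and gave 1.04 (0.893 to 1.22). The symbols took out 31.5% of X-linked and 13.7% of autosomal genes, of which 3.34% and 7.35% were marked. Leaving them out raised the marked share to 55.6% on the X and 62.0% on autosomes. The ratio of 0.767 thus also depends on which autosomal genes the symbols took out, and not all of those need be reproductive genes. With these genes left out on all chromosomes and CpG classes kept, the odds ratio was 1.05 (0.870 to 1.27), so both together may account for the promoter difference, though not tested for distal peaks. Marked X-linked promoters also had a lower median signal, 9.65 against 10.8 (difference −1.16, permutation p = 0.0306). A lower median had been set beforehand as the result for lower signal from 1 active X per cell. The comparison was not adjusted for promoter CpG content, whose median was 0.386 for X-linked and 0.569 for autosomal genes. It therefore cannot tell that hypothesis apart from CpG content, and the hypothesis stays open.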
